A study of Homo sapiens with 24 samples.

How the data were processed

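Polyadenylated RNA from 4 neuroblastoma cell lines, untreated or exposed to 1 µM GSK-J4 for 72 hours, was sequenced from 24 libraries in 8 groups of 3, and libraries were made with a strand-specific mRNA kit, per the labels' protocols. Sensitivity to GSK-J4 and MYCN status were taken from the labels. Read quality control with FastQC, alignment with STAR and testing with DESeq2 against hg38 are named per the submitters' processing notes, which give no versions. The annotation release, the counting tool, the use of strand in counting, the design formula and the direction of the contrast are not given in the sources used here. Whether the 3 replicates of a group came from separate cultures is not stated, so p-values measure the spread between these libraries, which may be technical.

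Each line has 1 table of the authors' own comparison, with 6 columns used here. The signal column holds, per the file headers, the mean over the line's libraries of counts normalized by the authors, each table on its own. The log2 fold change and its standard error, also on the log2 scale, are as deposited by the authors. The Wald statistic is a score as deposited, and the p-value and adjusted p-value are the authors'. Recomputing the p-values from the statistic and the adjusted values from the p-values gave no difference above 0.01 on the log10 scale in any table. In 3 tables the deposited score equalled fold change over standard error within 0.0001, and in the SK-N-BE(2) table it differed by more for 19488 genes, with a median difference of 0.000382. That table may have been made in another way, and the equations used below to remove the prior may then not hold for it, which would touch every prior-removed value of SK-N-BE(2) and the differences from it. The authors' deposited tables list 33561 genes for LAN5, 30271 for IMR5, 32760 for SK-N-FI and 29328 for SK-N-BE(2), of which 25753, 22594, 22576 and 13407 have an adjusted p-value. The lowest mean with an adjusted p was 1.12 in LAN5, 1.37 in IMR5, 1.98 in SK-N-FI and 26.2 in SK-N-BE(2), so weak genes were left untested in that last table more often than in the others. Depth per library is unknown, and no interval or floor that needs it is given.

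The table used for SK-N-FI carries a short name that is close to the line's name but not spelled like it, and no label gives the match. It was assigned by that likeness and by elimination, so every SK-N-FI value rests on this reading. The sign of the fold changes was read as GSK-J4 over untreated because the study is known to report induction of BBC3 by the compound and BBC3 is positive in the tables of the 3 sensitive lines. For SK-N-BE(2) the reading rests on MT2A and SLC30A1, which have the same sign there as in the other lines. A reversed table would turn every direction given for that line.

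The design fixed before the data were examined foresaw tables of comparisons as a possible case: fold changes and adjusted p-values are then reported as deposited and not tested again. No value per library was used, so replicate values, standard deviations, a count model, other normalizations, a replicate block and leaving out single libraries were not possible. The tests of differences between lines, planned as 1 fit over all libraries, were replaced by a Wald test on the per-line fold changes and standard errors. A gene was called at an adjusted p under 0.05.

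The deposited standard errors have a ceiling in each table and fall again for weak genes, as a normal prior on the fold change gives. The largest values were 0.539 in LAN5, 0.490 in IMR5, 0.428 in SK-N-FI and 0.0828 in SK-N-BE(2), so the deposited fold changes of SK-N-BE(2) were pulled toward 0 most strongly. To compare lines, the prior was removed: its precision was taken as 1 over the square of 2 times the largest standard error, and the equations for the shrunken fold change and its error were solved for each gene. The equations have a pair of solutions, and the one with the smaller error was taken for genes above the mean at which the running median of the standard error (501 genes) peaks, and the other below it. That mean was 3.15 in LAN5, 4.01 in IMR5, 4.66 in SK-N-FI and 134 in SK-N-BE(2). In SK-N-BE(2), genes near that mean and very variable genes, which can include MT2A, could belong to the other solution, with a larger fold change and error. Values made in this way are called prior-removed. Where values are not called prior-removed or a difference, they are those of the authors' deposited tables. For genes with a mean of at least 100, the median prior-removed standard error was 0.0976 in LAN5, 0.0970 in IMR5, 0.137 in SK-N-FI and 0.0821 in SK-N-BE(2).

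Differences of effect used genes with a mean of at least 100 in all 4 tables (8969 genes) and a two-sided Wald test on prior-removed values with Benjamini-Hochberg adjustment. The test was run on simulated folds for those 8969 genes, with 200 genes changed: for sensitive minus resistant lines it called 52 of 63 genes with a log2 difference of 0.5, all 67 with a difference of 1, all 70 with a difference of 2, and 12 of 8769 unchanged genes. The simulated errors came from the same inversion and were treated as known, so these rates are optimistic. On simulated tables for the 8969 genes the prior-removed folds had a correlation with the unshrunken ones that rounds to 1 or 0.999999 in each line. The same prior was put in and taken out there, so this checks the inversion only. It cannot show that the prior or the equations hold for the authors' tables. Expected overlaps are those of independent lists, and the lines have their own controls. They take every gene as equally easy to call, although strong genes are called more readily in each line, so they can be too low.

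The 23 gene lists (606 genes) were fixed before the data were examined, and 6 further lists were chosen after seeing the data. List members were counted as higher, lower or not called over all genes and again adjusted over the list alone. Camera was run on the deposited Wald statistics with a preset correlation of 0.01, for lists of at least 3 tested members. Benjamini-Hochberg adjustment was within a line, separately for the fixed lists and for those chosen after seeing the data. A correlation estimated from libraries and the fry test need values per library and were not run. In a simulated check with 20 sets, camera called the 1 shifted set and none of the others.

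Genes named in the text follow a rule fixed before the data were examined. It takes 10 genes always, the 5 largest rises and 5 largest falls per line among called genes with a mean of at least 100, up to 3 called members of each list with the largest change, 6 shared genes per direction, and 5 genes per direction and difference with the smallest adjusted p. The part of the rule that asks for no overlap between treated and untreated values could not be applied. Genes named beyond these were chosen after their values were seen: NCL and H1-2 in LAN5, HMOX1 in IMR5, EGLN3 in SK-N-FI, BCL6, EPHA2, LDHA, the mitochondrial ribosomal RNAs and the lipid synthesis genes outside the rule. Gene names were assigned by Ensembl identifier, since 28 symbols in the LAN5 table and 26 in the SK-N-BE(2) table had been turned into dates. Coordinates are those of GENCODE release 29 on GRCh38. Of the identifiers, 99.2% matched that annotation in each of the 4 tables. Metallothionein, histone, HLA, AKR1C and ribosomal protein genes share reads with near-identical copies, and mitochondrial genes with nuclear copies, so their values are uncertain to that extent.

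Alternatives were no filter on weak genes, a minimum mean of 50 or 300, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, centring of fold changes on the median, deposited in place of prior-removed folds, a reversed SK-N-BE(2) table for the differences from it, and leaving out a line. For camera they were a preset correlation of 0.05, ranks in place of values, and centring. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. No column belonged to a sample of another series.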

Results

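The study treated 4 human neuroblastoma cell lines with GSK-J4, a cell-permeable inhibitor of KDM6A and KDM6B, the enzymes that remove methyl groups from lysine 27 of histone H3. LAN5 and IMR5 carry amplified MYCN and SK-N-FI does not; the labels describe these 3 lines as sensitive to the compound. SK-N-BE(2), also MYCN-amplified, is described as resistant. Polyadenylated RNA was sequenced from untreated cultures and from cultures exposed to 1 µM GSK-J4 for 72 hours, with 3 libraries per group and 24 in all. The files used here hold one comparison table per line and no values of single libraries, so depth per library is unknown. The mean normalized counts of all genes summed to 15458940 in the authors' deposited table for LAN5, 19445359 for IMR5, 16089613 for SK-N-FI and 16036378 for SK-N-BE(2). Fold changes are read as treated over untreated, a direction that the tables do not state. It was set by BBC3 in the sensitive lines and by MT2A and SLC30A1 in SK-N-BE(2), so the signs of these genes there are part of the reading and not findings. Errors are standard errors, and adjusted p-values are Benjamini-Hochberg values of the Wald test.

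The targets of the compound and the genes chosen beforehand around them were examined first. KDM6B (chromosome 17, 7839904 to 7854796 on GRCh38, ENSG00000132510) rose in all 3 sensitive lines, with log2 fold changes of 0.55 ± 0.0772 in LAN5, 1.17 ± 0.09 in IMR5 and 0.83 ± 0.148 in SK-N-FI in the authors' deposited tables. KDM6A (chromosome X, 44873177 to 45112602, ENSG00000147050) also rose in these lines, by 0.50, 0.41 and 0.39 in the authors' deposited tables. EZH2, the methyltransferase that opposes these demethylases, fell, with log2 changes of -0.71, -0.24 and -0.66 in the authors' deposited tables for the same lines. In SK-N-BE(2) the values in the authors' deposited table were -0.05 ± 0.0603 for KDM6B, -0.04 ± 0.0699 for KDM6A and -0.13 ± 0.0525 for EZH2, and none of the 3 passed the test. BBC3 (chromosome 19, 47220822 to 47232766, ENSG00000105327), which encodes the pro-apoptotic protein PUMA, rose by 2.62 ± 0.246 in LAN5 (adjusted p = 2.99e-25), 3.31 ± 0.179 in IMR5 (1.06e-74) and 1.88 ± 0.206 in SK-N-FI (4.04e-18) in the authors' deposited tables. The authors' deposited table for SK-N-BE(2) gave BBC3 -0.01 ± 0.0723 (adjusted p = 0.978). Fold changes and errors of that line were shrunken most strongly, so for these genes their sizes cannot be set beside those of the other lines.

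**Figure D1:**
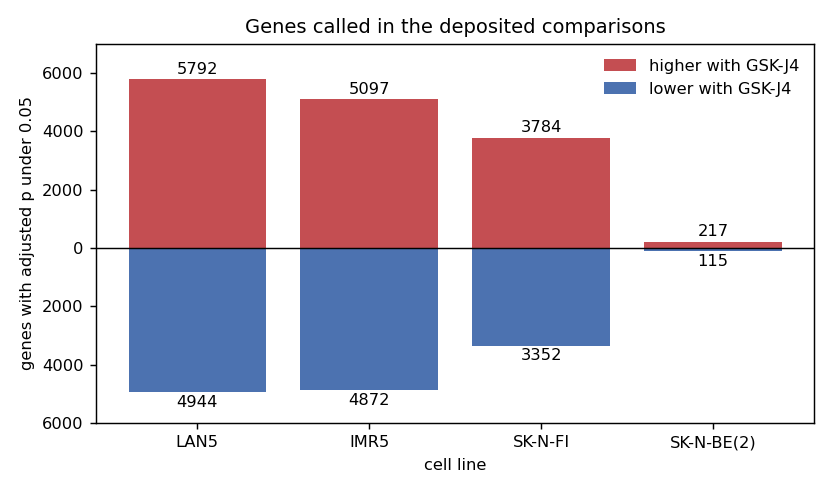
Number of genes with an adjusted p under 0.05 in each line's deposited comparison (y axis, genes), with genes higher with GSK-J4 above the zero line and lower ones below it. LAN5 had 5792 higher and 4944 lower genes, against 217 and 115 in SK-N-BE(2); with a mean of at least 50 the lower genes were the majority in LAN5, 4799 against 3736.

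LAN5 was compared with and without GSK-J4 to find which transcripts the compound changes in a sensitive MYCN-amplified line. HMOX1, the haem-degrading enzyme, had the largest rise among genes with a mean of at least 100, with a log2 fold change of 8.93 ± 0.249 (adjusted p = 5.65e-278) in the authors' deposited table. NUPR1, a stress-induced transcription regulator, followed with 6.78 ± 0.306, and the metallothionein gene MT2A with 6.60 ± 0.39, in the authors' deposited table. The proliferation marker MKI67 and the mitotic kinesin gene KIF20A fell by 3.39 ± 0.0825 and 3.35 ± 0.0828 on the log2 scale in the authors' deposited table. MYCN (chromosome 2, 15940564 to 15947007, ENSG00000134323) fell by 1.90 ± 0.0488 in the authors' deposited table. In all, 10736 of 25753 genes with an adjusted p passed the threshold, 5792 higher and 4944 lower. The balance depended on weak genes: with a mean of at least 50, 3736 were higher and 4799 lower.

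Among the gene lists fixed beforehand, 34 of 35 targets of the stress-response factors ATF4 and CHOP rose in LAN5 and none fell. Examples in the authors' deposited table were SLC7A11, the cystine transporter, at 5.51 ± 0.11, STC2 at 5.01 ± 0.164, and DDIT3, which encodes CHOP, at 2.77 ± 0.159. All 22 NRF2 targets rose, and 21 of 22 p53 targets did, with CDKN1A at 3.45 ± 0.0786 and FAS at 4.05 ± 0.186 in the authors' deposited table. Of the 54 G2/M genes 50 fell and 1 rose, and of the 48 G1/S genes 39 fell and 1 rose. The ribosome biogenesis and MYC target list had 29 of 36 members lower, including NCL at -1.13 ± 0.0642 in the authors' deposited table. The adrenergic list had 22 of 28 members lower, and the immediate early list 15 of 16 higher. Adjusted over the list alone, the counts that rose were 34 for ATF4/CHOP, 22 for NRF2, 21 for p53 and 15 for the immediate early genes. Those that fell were 51 for G2/M, 39 for G1/S, 29 for ribosome biogenesis and 22 for the adrenergic list. Limma's camera test on the Wald statistics called each of these 8 lists, with an adjusted p between 5.63e-09 for the immediate early genes and 2.01e-83 for the ATF4/CHOP targets. With a preset correlation of 0.05 in place of 0.01, the camera calls given here for this and the other lines were kept unless stated otherwise. Of 13 mitochondrially encoded mRNAs, a list included as a sign of RNA quality, 9 fell and 1 rose. The markers of other cell types did not move together. In the Schwann and glial list 3 of 7 tested members rose and none fell, in the fibroblast and muscle list 4 rose and 3 fell of 10, and in the immune and endothelial list 1 rose and 1 fell of 8.

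IMR5, the other sensitive MYCN-amplified line, was compared in the same way. The stress cytokine gene GDF15 had the largest rise, with a log2 fold change of 8.97 ± 0.251 (adjusted p = 5.62e-276) in the authors' deposited table, followed by MT2A at 7.19 ± 0.224. IGFBP5, an insulin-like growth factor binding protein gene, fell by 3.78 ± 0.149, and UHRF1, which helps to maintain DNA methylation through replication, fell by 2.45 ± 0.102 in the authors' deposited table. MYCN fell, with a log2 change of -1.07 ± 0.0706 in the authors' deposited table. In all, 9969 of 22594 genes passed the threshold, 5097 higher and 4872 lower.

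All 35 ATF4/CHOP targets rose in IMR5, with ATF5, a transcription factor gene, at 4.34 ± 0.235 and DDIT3 at 3.35 ± 0.275 in the authors' deposited table. Of the 21 p53 targets tested, 19 rose and none fell, with CDKN1A at 2.16 ± 0.0975 in the authors' deposited table. Of the 48 G1/S genes 47 fell, and of the 54 G2/M genes 45 fell and 3 rose. The ribosome biogenesis and MYC target list had 29 of 36 members lower and the immediate early list 14 of 16 higher, with EGR1 at 4.25 ± 0.332 in the authors' deposited table. The neuronal differentiation list had 21 of 33 members higher and 5 lower, led by the neurotrophin receptor gene NGFR at 4.29 ± 0.199 in the authors' deposited table. Adjusted over the list alone, 35, 19, 15 and 21 members rose in the ATF4/CHOP, p53, immediate early and neuronal lists, and 47, 46 and 30 fell in the G1/S, G2/M and ribosome biogenesis lists. Camera called each of these 7 lists, with an adjusted p between 6.39e-05 for the neuronal list and 6.79e-58 for the ATF4/CHOP targets. The NRF2 targets were split, with 7 of 20 higher and 8 lower (camera adjusted p = 0.947); their median deposited log2 change was below 0 and their mean above it. HMOX1 fell, with a log2 change of -0.93 ± 0.199 in the authors' deposited table. Of the 13 mitochondrially encoded mRNAs 8 fell and 2 rose. Among markers of other cell types 1 of 5 Schwann and glial genes rose, 2 of 8 fibroblast and muscle genes rose and 3 fell, and none of the 3 immune and endothelial genes tested was called.

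SK-N-FI was compared as the sensitive line without MYCN amplification. MT2A had the largest rise, at 4.96 ± 0.184 (adjusted p = 4.61e-156) in the authors' deposited table. PFKFB3, a regulator of glycolysis, rose by 4.74 ± 0.231 and PLOD2, a collagen-modifying enzyme induced by low oxygen, by 4.25 ± 0.253 in the authors' deposited table. Mitochondrial transcripts made up 3 of the 5 largest falls: MT-CO3, MT-CO2 and MT-CO1 fell, with log2 changes of -2.46 ± 0.138 for MT-CO2 and -2.43 ± 0.107 for MT-CO1 in the authors' deposited table. MYCN, with a mean normalized count of 116 in the authors' deposited table for this line, had a log2 change of -0.30 ± 0.203 (adjusted p = 0.268). In all, 7136 of 22576 genes passed the threshold, 3784 higher and 3352 lower.

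Of 34 ATF4/CHOP targets tested in SK-N-FI 32 rose, with STC2 at 3.34 ± 0.187 and PPP1R15A, a phosphatase subunit that ends the stress response, at 3.28 ± 0.107 in the authors' deposited table. Of 29 hypoxia-response genes 28 rose and 1 fell, including the peptide hormone gene ADM at 3.04 ± 0.239 in the authors' deposited table; the gene that fell was EGLN3 at -0.53 ± 0.122. Of the 48 G1/S genes 42 fell, and of the 54 G2/M genes 43 fell and 3 rose. NRF2 targets rose in 15 of 21 cases and fell in 2, and 13 of 28 genes of the mesenchymal neuroblastoma state rose while 1 fell. Only 7 of 21 p53 targets rose and 3 fell, and CDKN1A had a log2 change of 0.12 ± 0.107 (adjusted p = 0.439) in the authors' deposited table. Adjusted over the list alone, 33, 28, 15, 13 and 7 members rose in the ATF4/CHOP, hypoxia, NRF2, mesenchymal and p53 lists, and 42 and 44 fell in the G1/S and G2/M lists. Camera called the ATF4/CHOP, hypoxia, G1/S, G2/M, NRF2 and mesenchymal lists, with an adjusted p between 2.45e-06 for the mesenchymal list and 3.92e-65 for the hypoxia list. The p53 list had a camera adjusted p of 0.0523. Of 35 ribosome biogenesis and MYC targets, 10 rose and 9 fell (12 and 10 adjusted over the list alone), with a median deposited log2 change above 0, a mean of -0.00786 and a camera adjusted p of 0.961. All 13 mitochondrially encoded mRNAs fell, with a median log2 change of -1.93 in the deposited values (camera adjusted p = 9.16e-61). Markers of other cell types moved little as groups: 2 of 8 Schwann and glial genes rose, 3 rose and 2 fell of 10 fibroblast and muscle genes, and none of 3 immune and endothelial genes was called.

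**Figure D2:**
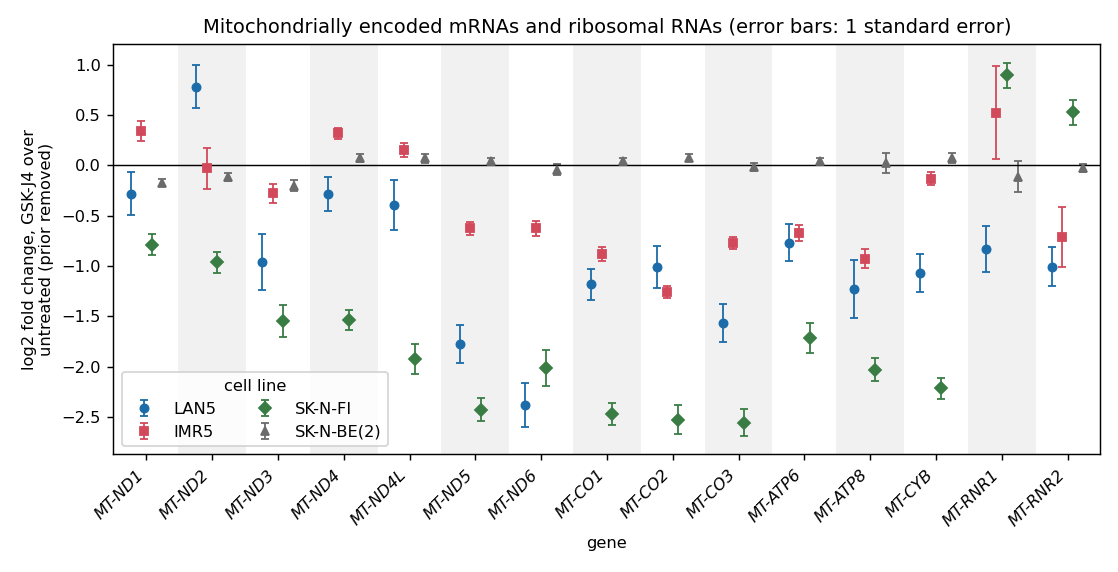
Log2 fold change (y axis, GSK-J4 over untreated, with the shrinkage of the deposited values removed) of the 13 mitochondrially encoded mRNAs and the pair of mitochondrial ribosomal RNAs, MT-RNR1 and MT-RNR2 (x axis), in each line, with bars of 1 standard error. In SK-N-FI the mRNAs lie between -2.55 and -0.79 and both ribosomal RNAs above 0.

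SK-N-BE(2) was compared as the line described as resistant, and 332 of 13407 genes passed the threshold, 217 higher and 115 lower. Of all 29328 genes listed for this line, tested or not, 1456 had an unadjusted p under 0.05. That share is no larger than the threshold itself would give without any change. MT2A had the largest rise, with a log2 fold change of 1.47 ± 0.0795 (adjusted p = 4.11e-68) in the authors' deposited table, and was the single gene with an absolute deposited log2 fold change of at least 1 past the threshold. SLC30A1, a zinc exporter gene, rose by 0.57 ± 0.0555 and PDGFRB, a growth factor receptor gene, by 0.53 ± 0.068 in the authors' deposited table. The transcriptional regulator gene SAMD11 fell by 0.68 ± 0.0821, BMF, a pro-apoptotic BCL-2 family member, by 0.61 ± 0.0799, and TH, which encodes the rate-limiting enzyme of catecholamine synthesis, by 0.59 ± 0.0524 in the authors' deposited table. Deposited fold changes of this table were shrunken more strongly than in the other 3, so their size cannot be set beside those of the other lines. MYCN had a log2 change of 0.11 ± 0.0391 (adjusted p = 0.157) in the authors' deposited table.

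In SK-N-BE(2) none of 34 ATF4/CHOP targets, 20 p53 targets and 54 G2/M genes was called, and of 48 G1/S genes 1 fell (RRM2, -0.19 ± 0.0448 in the authors' deposited table). The metallothionein and iron handling list had 6 of 12 members higher and none lower, a direction partly fixed by the reading of the table, since MT2A and SLC30A1 are members. The cholesterol synthesis list had 7 of 24 members higher and none lower, with INSIG1, a sterol sensor, at 0.28 ± 0.0555 in the authors' deposited table. The adrenergic list had 8 of 28 members lower and 1 higher, with the noradrenaline transporter gene SLC6A2 at -0.50 ± 0.0771 in the authors' deposited table. Adjusted over the list alone, 10 and 15 members rose in the metallothionein and cholesterol lists and 10 fell in the adrenergic list, while none of the ATF4/CHOP, p53 and G2/M genes passed. Camera called the metallothionein (adjusted p = 3.45e-36), cholesterol (7.87e-16) and adrenergic (6.4e-13) lists. The direction of the metallothionein call is no finding, and the call did not hold with ranks in place of values (adjusted p = 0.0531). Camera also called the ATF4/CHOP list as lower (adjusted p = 0.000562), with a median deposited log2 change of -0.0637 and no member called. Its calls of the interferon list as higher (adjusted p = 0.00533), the neuronal list as lower (0.0204) and the NRF2 list as higher (0.0464) were lost with a correlation of 0.05. Camera called the fibroblast and muscle markers, a list of other cell types, as higher (adjusted p = 7.2e-05), which held with a correlation of 0.05 and was lost with ranks (adjusted p = 0.291). Of these markers 3 of 8 rose and 1 fell, namely PDGFRB at 0.53, COL3A1 at 0.46 and COL1A1 at -0.27 among those named by the rule, in the authors' deposited table.

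**Figure D3:**
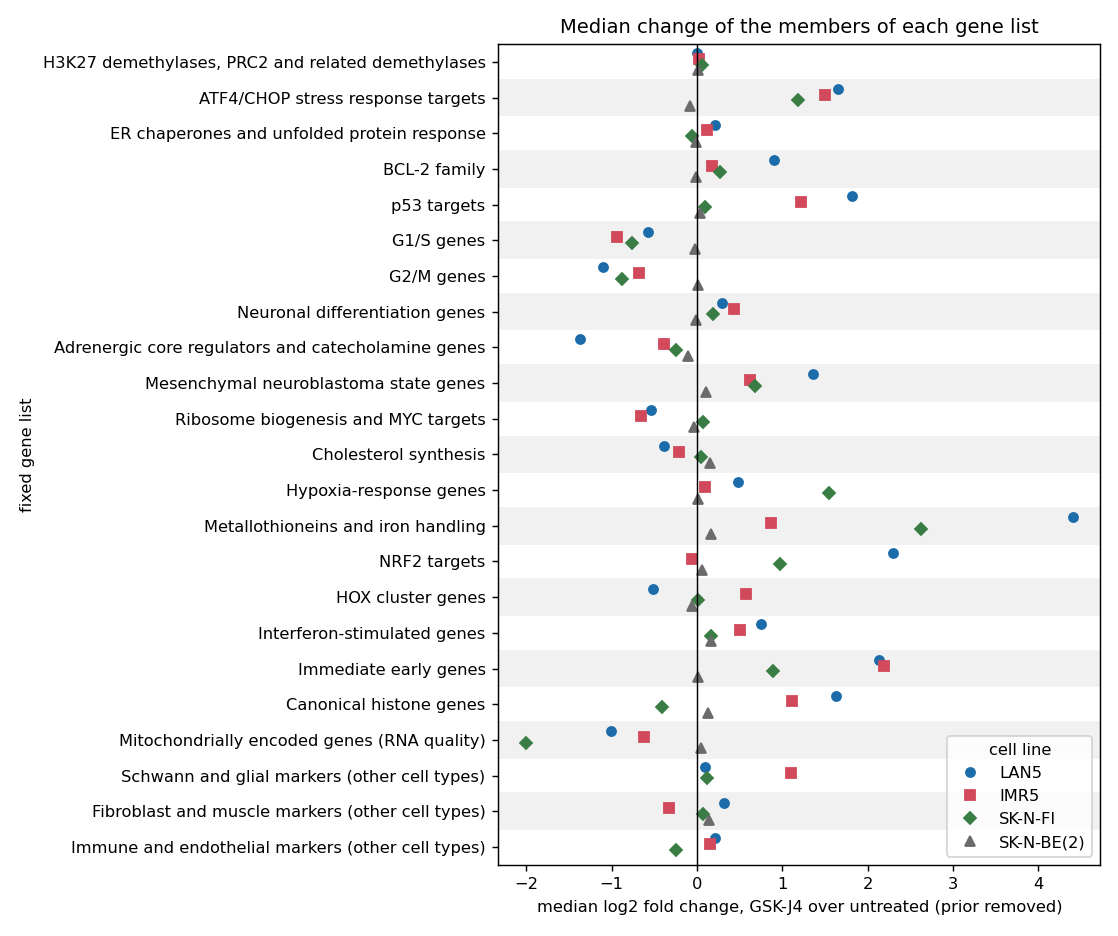
Median log2 fold change (x axis, GSK-J4 over untreated, with the shrinkage of the deposited values removed) of the tested members of each of the 23 fixed gene lists (y axis), with 1 symbol per line and lists of under 3 tested members left out. The ATF4/CHOP medians were 1.65, 1.51 and 1.18 in LAN5, IMR5 and SK-N-FI and -0.0768 in SK-N-BE(2), and the hypoxia median was highest in SK-N-FI, at 1.55. Weak genes are included in all medians.

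The response shared by the sensitive lines was counted as the genes called in the same direction in all 3. There were 931 such higher genes and 1084 such lower genes among 18599 genes tested in all 3 lines, where independent lists of the same lengths would give 202 and 189. These expected values take every gene as equally easy to call. Strong genes are called more readily in each line, so part of the excess can arise from that. To set fold changes of different lines side by side, the shrinkage of the deposited values was removed, as described for the processing. Ranked still by their deposited values, the higher genes with the largest smallest change were MT2A, GDF15, SLC30A1, STC2, PPP1R15A and SLC7A11. MT2A (chromosome 16, 56608199 to 56609497, ENSG00000125148) had prior-removed log2 fold changes of 7.81 ± 0.462 in LAN5, 7.61 ± 0.237 in IMR5, 5.22 ± 0.194 in SK-N-FI and 2.29 ± 0.124 in SK-N-BE(2); metallothionein genes are near-identical copies whose reads can be split between them. SLC7A11 (chromosome 4, 138164097 to 138242349, ENSG00000151012) had 5.57 ± 0.111, 3.58 ± 0.125, 2.70 ± 0.134 and -0.03 ± 0.0749 in the same order. The lower genes with the largest smallest change, ranked in the same way, were MKI67, UHRF1, MAP2K6, HMGB3, MCM6 and CCNB1. UHRF1 (chromosome 19, 4903080 to 4962154, ENSG00000276043) had -1.81 ± 0.0789 in LAN5, -2.47 ± 0.103 in IMR5, -2.18 ± 0.119 in SK-N-FI and -0.10 ± 0.0518 in SK-N-BE(2).

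Of the 834 shared higher genes also tested in SK-N-BE(2), 17 were called higher and 6 lower there, where independent lists would give 12.3 and 7.12. Of the 1076 shared lower genes, 18 were called lower and 14 higher, against 9.19 and 15.9 for independent lists. The 17 include MT2A and SLC30A1, whose shared sign was used to read the direction of the SK-N-BE(2) table and is therefore no result; BCL6 and EPHA2 were among the others. Those lower in the sensitive lines and higher in SK-N-BE(2) included the lipid synthesis genes FASN, ACLY, FADS2, SQLE and FDPS, which were singled out after their values were seen. Across genes, the deposited fold changes of LAN5 and IMR5 had a Pearson correlation of 0.401 (Spearman 0.348), those of LAN5 and SK-N-FI 0.309 (0.271), and those of IMR5 and SK-N-FI 0.349 (0.351). With SK-N-BE(2) the values were 0.1 (0.0576) for LAN5, 0.143 (0.127) for IMR5 and 0.0495 (0.0209) for SK-N-FI. Genes are not independent replicates, so no p-value is given for these 6 correlations. Among genes called in both lines, 76.8%, 74.7% and 80.4% had the same direction in the 3 pairs of sensitive lines, and 54.8%, 60.0% and 59.9% in the pairs with SK-N-BE(2), where MT2A and SLC30A1 count as the same direction by the reading. If that table were reversed, the last 3 shares would be 45.2%, 40.0% and 40.1%, and the correlations with SK-N-BE(2) would be negative.

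**Figure D4:**
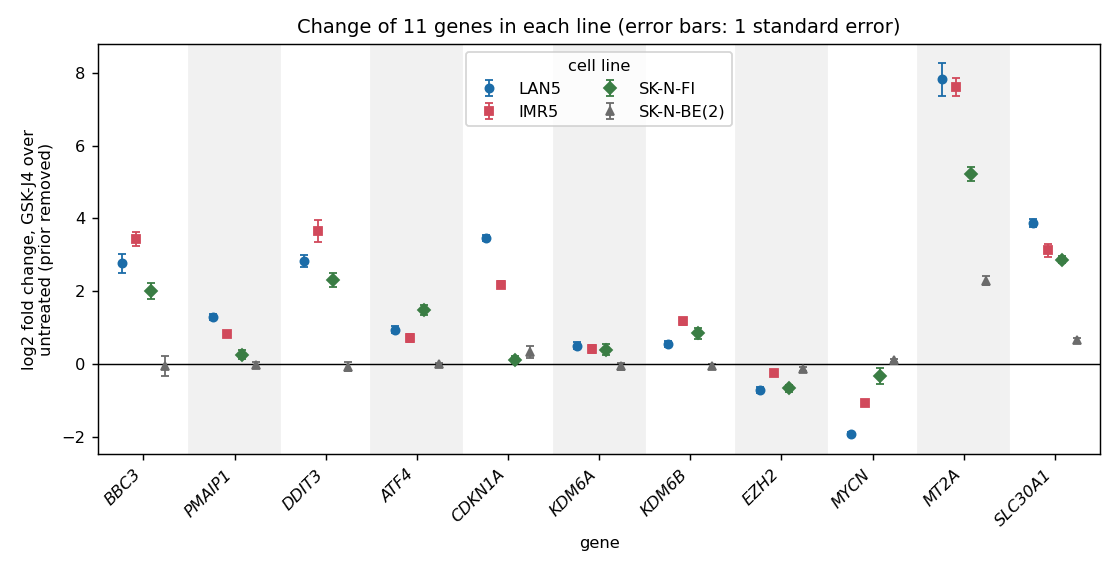
Log2 fold change (y axis, GSK-J4 over untreated, with the shrinkage of the deposited values removed) of 11 genes (x axis) in each line, with bars of 1 standard error. BBC3, DDIT3 and SLC30A1 lay above 1.9 in LAN5, IMR5 and SK-N-FI, and CDKN1A lay at 3.47 in LAN5 and 0.12 in SK-N-FI.

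The difference of the effect between the 3 sensitive lines and SK-N-BE(2) was tested for 8969 genes with a mean of at least 100 in every line, as the mean prior-removed fold change of the sensitive lines minus that of SK-N-BE(2). It passed the threshold for 5299 genes, with a positive difference in 2370 and a negative one in 2929. TRIB3 had a mean log2 fold change of 3.97 in the sensitive lines and -0.19 in SK-N-BE(2), a difference of 4.16 ± 0.132 (Wald test, adjusted p = 7.63e-213). The differences of DDIT3 and ATF4 were 3.01 ± 0.179 and 1.05 ± 0.0784. All 29 ATF4/CHOP targets in this test had a positive difference, as did 10 of 12 p53 targets and all 8 immediate early genes. A negative difference was found for all 47 G1/S genes, 48 of 54 G2/M genes, 22 of 33 ribosome biogenesis genes and 16 of 22 cholesterol synthesis genes. With the SK-N-BE(2) table reversed, the first 3 would be 47, 48 and 24, but only 6 cholesterol synthesis genes would be negative and 4 positive, with a median difference of 0.0081 in place of -0.41. The RNA quality list moved the same way, with 11 of 13 mitochondrially encoded mRNAs negative and a median difference of -1.21, larger in size than those of the G1/S (-0.80) and G2/M (-0.90) genes. KDM6B differed by 0.91 ± 0.0963 (adjusted p = 4.31e-20) and KDM6A by 0.50 ± 0.113 (3.43e-05). MYCN differed by -1.22 ± 0.0878, although its change did not pass the threshold in SK-N-FI. The p53 and ribosome biogenesis differences rest mainly on LAN5 and IMR5. In SK-N-FI the 12 p53 targets had a median prior-removed change of -0.138, against 1.23 for the mean of LAN5 and IMR5. For the 33 ribosome biogenesis genes these medians were 0.0719 and -0.550, and for the 22 cholesterol synthesis genes 0.0755 and -0.286. BBC3 was left out of this test, since its mean normalized count in the authors' deposited table for SK-N-BE(2) was 42.6. There is 1 resistant line, so the contrast is between these lines and not between classes of sensitivity.

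The difference between the MYCN-amplified sensitive lines and SK-N-FI was tested on the same genes, as the mean of LAN5 and IMR5 minus SK-N-FI. It passed the threshold for 4242 genes, positive in 1694 and negative in 2548. ASS1, which encodes the arginine synthesis enzyme, had a mean of 2.54 in LAN5 and IMR5 and -0.54 in SK-N-FI, a difference of 3.08 ± 0.124 (Wald test, adjusted p = 1.63e-131). That mean rests mainly on LAN5, where the prior-removed fold change of ASS1 was 4.64 ± 0.121, against 0.44 ± 0.0524 in IMR5. CDKN1A differed by 2.71 ± 0.126 and RRM2B, another p53 target, by 2.38 ± 0.114. PFKFB3 differed by -5.27 ± 0.258 and SLC2A1, a glucose transporter gene, by -2.12 ± 0.121. By list, 10 of 12 p53 targets had a positive difference and none a negative one. A negative difference was found for 18 of 21 hypoxia-response genes and 25 of 33 ribosome biogenesis genes, and a positive one for all 13 mitochondrial mRNAs. KDM6B, KDM6A and EZH2 had differences of 0.01 ± 0.164, 0.06 ± 0.16 and 0.19 ± 0.101, and none passed. With 1 wild-type line, MYCN status and cell line cannot be told apart.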

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

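The results below were singled out because the effect of GSK-J4 differed between lines by a test of the difference itself. Of the tests weighed here, those on precision and on exchanged libraries were chosen after the result was seen. For the one on shrinkage, what it would show was written before the tested value was seen.

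Between the sensitive lines and SK-N-BE(2), the prior-removed effect differed for 5299 of 8969 genes. The rule took the genes with the smallest adjusted p. Differences (sensitive minus resistant, log2) were 3.98 ± 0.104 for SLC7A11, 4.16 ± 0.132 for TRIB3, 3.90 ± 0.125 for STC2 and 2.34 ± 0.0873 for SLC3A2, which encode amino acid transporters, a pseudokinase and a secreted glycoprotein and belong to the ATF4/CHOP list. SLC30A1, the zinc exporter gene, differed by 2.64 ± 0.0992, with a rise in SK-N-BE(2) that rests on how the direction of that table was read. Among cell cycle genes, KIF20A differed by -2.30 ± 0.077, UHRF1 by -2.06 ± 0.0783, CCNB1 by -1.86 ± 0.0711 and MKI67 by -2.58 ± 0.103, and the chromatin gene HMGB3 by -1.64 ± 0.07. Each kept its direction and call under every alternative run for it, namely other filters, thresholds, centring, deposited folds, a reversed SK-N-BE(2) table and leaving out a sensitive line.

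Between the MYCN-amplified sensitive lines and SK-N-FI, the effect differed for 4242 of 8969 genes. Differences (amplified minus wild-type, log2) were 3.08 for ASS1, 2.71 for CDKN1A, 3.86 for NGFR, 2.64 for LMNA and 2.38 for RRM2B. Negative differences were -5.27 for PFKFB3, -2.73 for the peptide-amidating enzyme gene PAM, -3.44 for IGFBP5, -2.12 for SLC2A1 and -2.22 for LRRN3. The wild-type group is a single line, so these values describe SK-N-FI against LAN5 and IMR5.

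SK-N-BE(2) had 332 called genes where the other lines had 7136 to 10736. On lower precision, its median prior-removed standard error was 0.0821, below the 0.0970 to 0.137 of the other lines. This does not decide the point: genes above a mean of 134 were given the smaller solution, so errors above 0.166 could not show. Under the equations used, the prior cancels from the Wald statistic, so stronger shrinkage could not lower the number of calls. The comparison written beforehand therefore does not test it as a cause of the count. Prior removed, the 1759 shared genes with a mean of at least 100 in SK-N-BE(2) had a median absolute fold change of 0.0607 there. In the sensitive lines it was 0.708, a ratio of 0.0857. These genes were picked for being called in the sensitive lines, which favours a low ratio. All of this assumes that the prior removed is the one used for this table. An exchange of 1 treated with 1 untreated library was argued against: it adds spread in proportion to a change and leaves a Wald statistic of about 0.707 for a change of any size, while 66 genes had an absolute statistic of at least 5, as far as each gene's error follows its own spread; a ratio of standard errors set out beforehand (0.996) was void, since the method cannot show errors above 0.166. Lower precision stays open, and so do a lower effective exposure of these cultures and the resistance that the labels name, which were not tested.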

How the results depend on the processing

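Settings with a prior-removed size of change, centring, a minimum mean of 300, deposited folds, a reversed SK-N-BE(2) table, or another camera correlation or statistic were chosen after seeing the data. No paired analysis was possible because the tables hold no values per library. For the same reason other tools, other normalizations, other pseudocounts, leaving out replicates, an estimated correlation in camera and other splits of the samples were not run, and whether chance groupings of the libraries could give as many genes is unknown. With an absolute deposited log2 fold change of at least 1, the called genes numbered 4054 in LAN5, 3110 in IMR5, 1769 in SK-N-FI and 1 in SK-N-BE(2), and with the prior-removed fold change 4198, 3320, 2086 and 11; the genes shared by the sensitive lines numbered 206 and 225. These settings add a criterion, so lower counts follow from their construction. An adjusted p under 0.01 gave 170 genes in SK-N-BE(2). The median correlation among the sensitive lines was 0.349 as reported, 0.437 with a mean of at least 50, 0.375 over genes called in at least 1 line and 0.464 with prior-removed folds, and the median correlation with SK-N-BE(2) was 0.1 as reported, 0.0868, 0.115 and 0.0687 under the same settings; the cause was not tested. The other 38 counts stayed within 1.5 times the reported one. In LAN5 the share of higher genes among those called was 53.9%, 43.8% with a mean of at least 50 and 61.2% when centred on the median log2 fold change of -0.0871. Of 90 tests of lists by camera 46 passed, with 37 at a correlation of 0.05, 40 with ranks and 45 when centred. Among the fixed lists, single genes and named differences run through the alternatives, none past the threshold changed direction. Other differences did turn with the SK-N-BE(2) table reversed: in the fatty acid list positive ones went from 0 to 3 and negative ones from 10 to 6. The majority of LAN5 calls turned from higher to lower with a mean of at least 50. Some lists that were not called changed sign with ranks, such as the NRF2 list in IMR5. Among single genes and lists 566 values kept their side of the threshold, 18 lost it and 1 gained it. Those lost include, at a correlation of 0.05, the BCL-2 list in LAN5 (adjusted p = 0.0803) and SK-N-FI (0.0508), the neuronal list in LAN5 (0.0754) and SK-N-BE(2) (0.165), the adrenergic list in IMR5 (0.0569) and the interferon list in LAN5 (0.0842) and SK-N-BE(2) (0.0519).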

Other observations

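The lists not described above were counted in the same way, and many were split or not called as groups. The neuronal list had 18 of 35 members higher and 9 lower in LAN5 (camera adjusted p = 0.00804, and 0.0754 with a correlation of 0.05) and the mesenchymal list 17 of 29 higher and 3 lower (0.000296), with FOSL1 at 4.71 ± 0.251 in the authors' deposited table. Weak genes weigh on the mesenchymal list. Its median prior-removed change in LAN5 was 1.36, and 0.614 for the 14 members with a mean of at least 100. In IMR5 it was 0.623, and 0.0164 for the 15 such members. Canonical histone genes, whose copies share reads, rose in 17 of 27 cases in LAN5 and 7 of 18 in IMR5, while 6 of 18 fell and 3 rose in SK-N-FI; camera called them in LAN5 (adjusted p = 3.01e-06) and not in IMR5 (0.225) or SK-N-FI (0.434). H1-2 was at 2.10 ± 0.142, 2.61 ± 0.21 and -1.09 ± 0.149 in the authors' deposited tables for those lines. Of the BCL-2 family 9 of 15 rose and 4 fell in LAN5, 5 rose and 4 fell in IMR5, and 6 rose and 1 fell in SK-N-FI. HRK, another pro-apoptotic member, was at 3.06 ± 0.25, 1.35 ± 0.161 and 2.44 ± 0.241 in the authors' deposited tables, while the single call in SK-N-BE(2) was the fall of BMF. Chaperones of the endoplasmic reticulum were split, with 14 higher and 7 lower in LAN5, 11 and 10 in IMR5 and 6 and 7 in SK-N-FI, and camera called them as higher in LAN5 (adjusted p = 0.0045, 0.0436 with a correlation of 0.05, lost with ranks at 0.11) and not in IMR5 (adjusted p = 0.096) or SK-N-FI (0.961). The list of H3K27 demethylases and related genes was split too, with 9 higher and 8 lower, 7 and 8, and 7 and 6 (camera adjusted p = 0.978, 0.636 and 0.935). HOX genes gave 1 higher and 4 lower of 13 in LAN5, 6 and 0 of 15 in IMR5, and 3 and 0 of 21 in SK-N-FI (camera adjusted p = 0.212, 0.367 and 0.935), and interferon-stimulated genes 13 and 2 of 31, 10 and 3 of 26, and 4 and 8 of 35. Hypoxia-response genes gave 16 higher and 3 lower in LAN5 and 10 and 11 in IMR5. Camera called them as higher in LAN5 (adjusted p = 5.9e-06) and did not call them in IMR5 (0.741). Metallothionein and iron genes gave 12 of 15 higher in LAN5, 9 of 10 in IMR5 and 12 of 16 in SK-N-FI, with 1 lower in each. Camera called that list as higher in all 3 (adjusted p = 4.47e-14, 3.28e-11 and 2.575e-38). These calls of both lists held with ranks. Adrenergic genes gave 5 higher and 14 lower of 26 in IMR5 and 6 and 10 of 26 in SK-N-FI, neuronal genes 14 and 8 of 33 in SK-N-FI and 1 and 5 of 34 in SK-N-BE(2), and mesenchymal genes 13 and 5 of 28 in IMR5 and 2 and 0 of 19 in SK-N-BE(2). Of 15 immediate early genes 11 rose in SK-N-FI, while 2 of 13, EGR1 and JUNB, fell in SK-N-BE(2), as did 2 mitochondrial mRNAs. Adjusted over the list alone, the counts of this paragraph changed by at most 2 per direction.

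Fatty acid synthesis genes moved in opposite directions in SK-N-BE(2) and in LAN5 and IMR5, while in SK-N-FI the list was not called; were the SK-N-BE(2) table reversed, the same genes would be lower in it too. Of 11 fatty acid synthesis genes, a list chosen after seeing the data, 9 rose and none fell in SK-N-BE(2), while 8 fell and 2 rose in LAN5, 7 fell and 1 rose in IMR5, and 5 fell and 2 rose in SK-N-FI. Camera gave an adjusted p of 2.4e-24 (higher) in SK-N-BE(2), 0.000507 and 0.00021 (lower) in LAN5 and IMR5, and 0.0636 in SK-N-FI. As the list was chosen from these same data, these values describe it and are no independent support. The desaturase gene SCD was at -1.03 ± 0.0574 in LAN5, -1.04 ± 0.0643 in IMR5, 0.10 ± 0.107 in SK-N-FI and 0.32 ± 0.0357 in SK-N-BE(2) in the authors' deposited tables. The sensitive-minus-resistant difference was negative for 10 of the 11 genes, with none positive, and would be negative for 6 and positive for 3 with the table reversed. Cholesterol synthesis genes fell in 13 of 25 cases in LAN5, 11 of 25 in IMR5 and 8 of 24 in SK-N-FI, and rose in 4, 3 and 5. Camera called that list as lower in LAN5 (adjusted p = 0.0448, and 0.145 with a correlation of 0.05) and not in IMR5 (0.248) or SK-N-FI (0.434). Adjusted over the list alone, counts of this paragraph changed by at most 1. Of 18 glycolysis genes, also a list chosen after seeing the data, 17 rose in SK-N-FI, while in IMR5 10 of 17 tested fell and 3 rose. In LAN5 the list was split, with 7 of 17 higher and 6 lower. In SK-N-BE(2) none of the 18 was called, though camera called the list as higher (adjusted p = 0.0097). LDHA, which makes lactate, was at 0.91 ± 0.102 in SK-N-FI, -1.48 ± 0.0949 in IMR5 and -0.70 ± 0.0699 in LAN5 in the authors' deposited tables. The p53 targets rose in LAN5 and IMR5 and mostly did not in the other lines.

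All tests of the next 2 patterns were chosen after the results were seen. The mitochondrially encoded mRNAs fell in SK-N-FI, with a median prior-removed log2 change of -2.01, and a loss of all mitochondrial RNA may be the cause. Against this, both mitochondrial ribosomal RNAs rose in SK-N-FI and lay at least 2.53 above the mRNA median, although polyadenylated RNA captures them unevenly. In LAN5 the ribosomal RNAs lay 0.00468 and 0.179 above the mRNA median of -1.01, but the 13 mRNAs ran from -2.38 to 0.782 and 4 lay above the median by over 0.5 and 2 standard errors, which argues against an equal loss as the whole cause. In IMR5, with gaps of -0.0873 and 1.15, the mRNAs ran from -1.26 to 0.341 and 4 lay above the median of -0.624 in the same way. Capture that differs between mRNA and ribosomal RNA, and an effect of the compound, remain open and were not tested.

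Ribosomal protein genes, a list chosen after seeing the data, rose in 71 of 77 cases in SK-N-FI and 65 of 77 in IMR5, where 3 fell, while in LAN5 20 fell and 5 rose; adjusted over the list alone, 72 and 66 rose and 17 fell. A bias by transcript length was argued against: their median prior-removed log2 change was 0.731 in SK-N-FI, where 10000 random sets matched on length and mean gave medians between -0.127 and 0.0766, and 0.402 in IMR5, where they gave -0.431 to -0.203 (95% ranges). Other genes with a terminal oligopyrimidine tract, whose translation is controlled together with that of ribosomal proteins, had medians of 0.684 in SK-N-FI and 0.329 in IMR5, above the ranges of sets matched on mean alone, -0.257 to 0.132 and -0.449 to 0.0055. A candidate explanation in SK-N-FI and IMR5 is therefore a change common to this class of transcripts, as a hypothesis found and tested on the same data. In LAN5 camera called both lists as lower (adjusted p = 0.0336 and 0.029), and neither with a correlation of 0.05. In SK-N-BE(2) camera called the ribosomal protein list as lower (adjusted p = 0.000145), with 1 of 77 genes called. The other terminal oligopyrimidine genes were not called as a list there (adjusted p = 0.5495). Reads shared with pseudogenes, which could differ by line, were not tested.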
